A study of Mus musculus with 12 samples.

How the data were processed

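Brain T cells of 9-month-old female mice of 4 genotypes were measured in 6 pools, each with a 5' gene expression library and a T cell receptor library: 2 WT pools, 2 5XFAD pools, 1 PS19 pool and 1 PS-5X pool. Per the labels' protocols, half-brains of perfused mice were digested with collagenase IV and DNase, lymphocytes were taken from Percoll, and CD4+, CD8+ and γδ+ T cells were sorted before loading. The PS19 line was on a mixed background per the labels. The authors processed the reads with Cell Ranger 6.0.1, per the file headers and the submitters' processing notes, which name the builds GRCm38 and mm10 without a role. The deposited gene expression matrix holds counts, UMI counts per gene and barcode, and joins the 6 pools with a pool number after each barcode. Whether reads were thinned to equal depth when the pools were joined was not stated. The deposited receptor tables hold, per the file headers, UMI counts per contig and counts of cells per clonotype. The other deposited column used, the authors' pool name of each contig, is text and tied each barcode suffix to 1 pool. Every contig listed was cell-associated, high confidence, full length and productive, as tested on the table.

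The matrix held 854 barcodes for WT-1, 3693 for WT-2, 2658 for 5XFAD-1, 2347 for 5XFAD-2, 2449 for PS19 and 6373 for PS-5X, with 5883210, 22257591, 18233631, 16124784, 17848370 and 38616794 UMIs. Cells with 500 or more genes and at most 10% mitochondrial UMIs were kept. Doublets were scored per pool with Scrublet, run in scanpy 1.11.5. Its automatic threshold marked under 1.1% of barcodes in every pool, so the highest-scoring barcodes up to the number expected at 0.8% per 1000 barcodes were removed (6, 109, 56, 44, 48 and 325). Cells were clustered with Leiden (leidenalg 0.10.2, resolution 1.0, 2000 variable genes, 30 principal components, 15 neighbours) and clusters were named by lists of marker genes: at least 3 markers of a lineage, with its lead marker (Cd8b1, Cd4 or Trdc) among them, in at least 50% of cells each, and the lead markers of the other lineages in under 20%. The named classes held 470, 2254, 1663, 1377, 1531 and 4082 CD8 T cells, 153, 762, 439, 378, 532 and 1068 CD4 T cells and 38, 161, 160, 145, 78 and 279 γδ T cells in the order above. UMIs per CD8 sum ran from 3824809 to 26057021, per CD4 sum from 1060445 to 5642417 and per γδ sum from 290754 to 1602885, and the biological coefficient of variation between pools was 10.8%, 12.8% and 12.5%.

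UMIs were summed per pool and class and tested with edgeR 4.0.16 in R 4.3.3 (TMM, filterByExpr, quasi-likelihood F test, Benjamini-Hochberg adjusted p of 0.05). Amyloid (5XFAD-1, 5XFAD-2 and PS-5X against WT-1, WT-2 and PS19) was fitted with tau as a second term and tau with amyloid, 3 residual degrees of freedom each. 5XFAD against WT used 1 coefficient per genotype, 2 residual degrees of freedom. Expanded and singleton CD8 T cells were compared as 2 sums per pool with pool as block. Gene lists were tested with camera in limma 3.58.1 (preset correlation 0.01, beside a correlation estimated per list) and counted over all genes and adjusted over the list alone: cytotoxic effector, inhibitory receptor and exhaustion, naive and central memory, tissue residency, type I interferon response, interferon γ response and antigen presentation, early T cell receptor response, dissociation and heat shock, chemokine receptors and integrins, cell cycle, glycolysis, mitochondrially encoded, microglia and macrophage, brain parenchyma, B and plasma cell, red blood cell and NK cell. Named genes were, of those that passed with the same direction in PS-5X against PS19, 5XFAD-1 against WT-1 and 5XFAD-2 against WT-2 and a mean of at least 20 CPM, the 10 with the largest rise and the 10 with the largest fall; with fewer than 5 of these, the 5 with the smallest p in each direction; and a fixed set of T cell genes. Named CPM values are scaled by TMM. The comparisons, lists, naming rule and first alternatives were fixed before the data were examined.

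Clones were the authors' clonotypes, counted within each pool, and a clone was expanded at 2 or more cells. Shares were compared between pools with and without amyloid by an exact permutation test, two-sided, with Clopper-Pearson 95% intervals for single pools. The share of expanded cells was also drawn at 447 cells per pool (100 seeded draws). A receptor was shared between pools when V genes and CDR3 nucleotides of both chains were identical. The number of large clones, 5 or more cells, expected in WT-1 came from 100000 simulated draws in proportion to clone size. V gene usage was tested with edgeR on numbers of clones. For single pools, CPM of genes with at least 50 CPM in 1 of the 2 pools and at least 10 UMIs in both were given with exact Poisson intervals.

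Alternatives tried were DESeq2 1.42.0 (Wald test, and its size factors in edgeR), no gene filter beyond 1 UMI, a replicate block, each pool left out in turn, doublets kept, classes from the UMIs of each cell, UMIs thinned to the smallest sum, the same number of cells from each pool, only cells with a receptor, other clone sizes and clone definitions, other clustering resolutions (0.6 and 1.6) and a looser cell filter (200 genes, 20%). The replicate block was the sequencing run, since per the labels WT-2 and 5XFAD-2 came from a run of their own. As a check of that pairing, the log2 difference of WT-1 from WT-2 correlated over genes with that of 5XFAD-1 from 5XFAD-2 at 0.26 in CD8, 0.18 in CD4 and 0.12 in γδ T cells. Since WT-1 carried receptors of 5XFAD-1, mixed cells alone would correlate these differences, so the values do not show a run effect. Chosen after the data were seen were the fits with the replicate block and without WT-1, those without WT-1 cells that carried receptors of other pools, the γδ fit without cells with an αβ receptor contig and the mean of the differences within runs. So were the CD4 share of T cells, tau in CD4 and γδ T cells, and the interactions and the comparisons between lineages, with and without WT-1.

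The tests were tested on simulated data with the sizes and spread of these sums. Counts were drawn independently per gene, without cells mixed between pools or a difference between runs, so recovery in the real sums may be lower. For changes of 1.5-, 2- and 4-fold the CD8 amyloid test recovered 43.3%, 71.6% and 95.5% (13 of 153 calls were false), tau 37.3%, 70.1% and 93.9%, 5XFAD against WT 23.9%, 68.7% and 87.9%, CD4 amyloid 16.4%, 67.2% and 97.0%, γδ amyloid 7.46%, 50.7% and 89.4%, and expanded against singleton 77.6%, 82.1% and 93.9%. V gene usage recovered 55% of 2-fold changes. In the simulation of 5XFAD against WT 18 of 138 calls were false. DESeq2 size factors moved the median log2 value of all genes by at most 0.01. Left out were cells of unnamed clusters and the consensus receptor sequences, whose chains the contig table holds. Scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.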

Results

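T cells from half-brains of 9-month-old female mice were read as 6 pools, each a separate sample: WT-1 (10 mice), WT-2 (8), 5XFAD-1 (4) and 5XFAD-2 (3), which carry the amyloid transgenes, PS19 (4), which carries mutant tau, and PS-5X (4), which carries both. After filtering, 829 cells remained in WT-1, 3533 in WT-2, 2549 in 5XFAD-1, 2216 in 5XFAD-2, 2355 in PS19 and 5898 in PS-5X. CD8 T cells (Cd8a, Cd8b1) were 10 clusters, CD4 T cells (Cd4, Cd40lg) 4 clusters with a Foxp3 cluster among them, and γδ T cells 1 cluster marked by Il17a, Trdv4 and Cd163l1, the profile of IL-17-producing γδ cells. WT-2 and 5XFAD-2 were sequenced in a run of their own and the other 4 pools in a common run, so values within runs are given beside pooled values. Unnamed clusters, such as low-UMI, cycling and NK-like cells, held 7.95% (PS-5X) to 20.3% (WT-1) of kept cells and stayed out of the comparisons.

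WT-1 carried receptors of other pools. Of its 559 cells with both chains, 169 (30.2%, 26.4 to 34.2, Clopper-Pearson, counting error only) had α and β sequences identical in nucleotides to a receptor of another pool: 110 cells shared 58 receptors with 5XFAD-1, 58 cells shared 42 with PS19 and 4 cells shared 2 with PS-5X. The share was 146 of 387 CD8 T cells (37.7%) and 16 of 130 CD4 T cells (12.3%). PS19 and PS-5X shared 6 receptors, and the other pairs of pools shared 0. The plot of shared receptors gives every pair. The shares and the counts of called genes were therefore also computed without that pool.

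**Figure D1:**
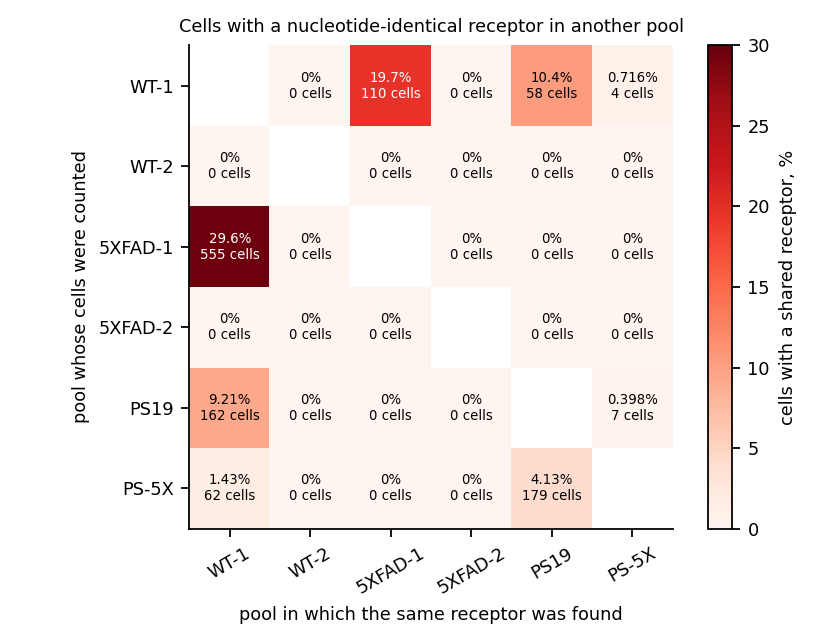
Share of each pool's cells (rows, with both chains) whose nucleotide-identical α and β receptor was also found in another pool (columns), with the number of cells. Of WT-1 cells, 19.7% shared a receptor with 5XFAD-1 and 10.4% with PS19.

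The make-up of the sorted T cells differed by a few percentage points between genotypes, most for CD4 T cells. These were 19.7 ± 0.24% (mean ± SD, n = 3 pools) of CD4+, CD8+ and γδ+ sorted T cells in pools with the amyloid transgenes and 24.0 ± 0.85% without (n = 3), a difference of -4.34 percentage points (exact permutation test, two-sided, p = 0.10, the smallest that 3 against 3 pools can give; -4.46 points within the common run, -4.09 within the separate run). All 3 amyloid pools lay below all 3 others, an order that chance gives in 10% of splits counting both directions. It was lost with classes from the UMIs of each cell (-3.31 points, exact permutation test, p = 0.20) and at resolution 1.6 (-4.75 points, p = 0.20). CD8 T cells were 73.7 ± 1.37% against 71.2 ± 0.29%, a difference of 2.54 points (exact permutation test, two-sided, p = 0.10, n = 3 and 3; 3.05 and 1.53 points within the runs). With classes from the UMIs of each cell it was 2.36 points (exact permutation test, p = 0.60), and at resolution 1.6 p was 0.20. γδ T cells were 6.61 ± 1.31% against 4.82 ± 1.07%, a difference of 1.79 points (exact permutation test, two-sided, p = 0.20, n = 3 and 3; 1.41 and 2.56 points within the runs). The sort and the mixing of sorted cells can set such shares. Leaving out each pool in turn gave -4.76 to -3.91 points for CD4 T cells, 1.81 to 3.17 for CD8 T cells and 1.21 to 2.53 for γδ T cells.

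CD8 T cells of the amyloid pools were more often in expanded clones. In clones of 2 or more cells were 43.8% (41.3 to 46.3, Clopper-Pearson, counting error only) of the CD8 T cells with a receptor in 5XFAD-1, 40.9% (38.1 to 43.7) in 5XFAD-2 and 47.3% (45.7 to 48.9) in PS-5X, against 21.5% (17.8 to 25.6) in WT-1, 33.0% (31.0 to 35.1) in WT-2 and 24.0% (21.8 to 26.3) in PS19. In WT-1, 80 of the 96 cells in expanded clones carried receptors of other pools, and without such cells its share was 5.32% (3.07 to 8.49) and the difference between the means 23.2 points. That step shifts WT-1 toward singletons, so the 5.32% can be too low and the 23.2 points too large. The means were 44.0 ± 3.23% and 26.2 ± 6.07% (SD, n = 3 pools each), 17.8 points apart (exact permutation test, two-sided, p = 0.10), with 22.8 points within the common run and 7.86 within the separate run. PS-5X and PS19, both of 4 mice and both with tau, stood at 47.3% and 24.0%, and all 3 amyloid pools lay above all 3 others, an order that chance gives in 10% of splits counting both directions. At 447 cells from every pool the shares were 33.7% in 5XFAD-1, 33.5% in 5XFAD-2 and 32.7% in PS-5X against 21.5% in WT-1, 23.2% in WT-2 and 16.3% in PS19, a difference of 13 points (exact permutation test, p = 0.10, n = 3 and 3; 13.5 points without WT-1). Without WT-1 the difference over all cells was 15.5 points, the lowest of 15.5 to 21.3 with each pool left out in turn.

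**Figure D2:**
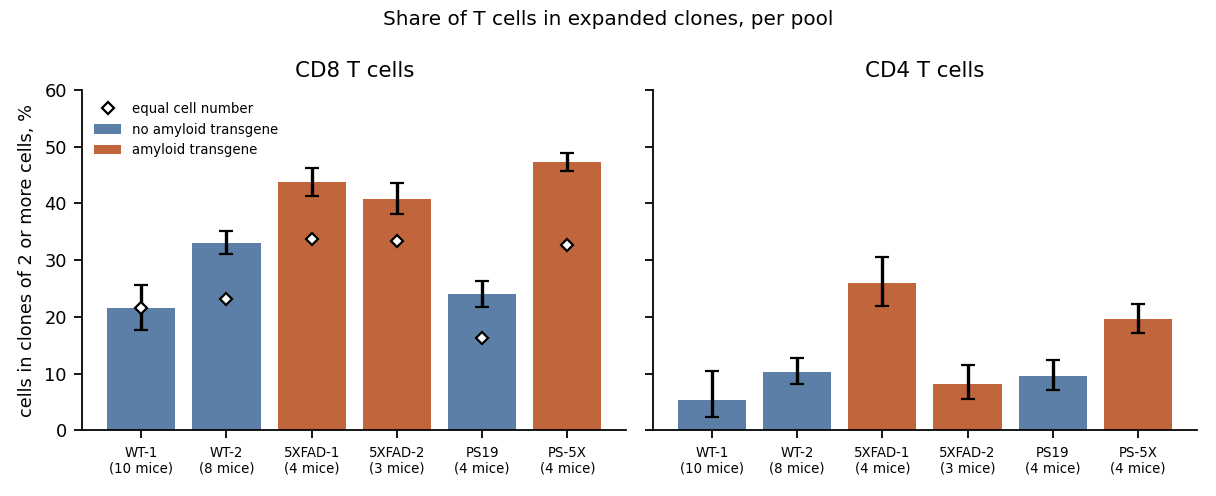
Share of CD8 and CD4 T cells in clones of 2 or more cells, by pool; error bars are 95% Clopper-Pearson intervals (counting error only), diamonds the share at 447 cells per pool. The amyloid pools held 40.9% to 47.3% of CD8 T cells in expanded clones and the other pools 21.5% to 33.0%.

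Single clones reached far larger sizes in 2 of the amyloid pools. The largest CD8 clone of PS-5X had 351 cells (9.39% of its CD8 T cells with a receptor, 8.47 to 10.4; TRBV29 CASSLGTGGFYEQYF with TRAV14D-2 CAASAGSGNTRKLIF) and that of 5XFAD-1 152 cells (9.70%, 8.28 to 11.3; TRBV29 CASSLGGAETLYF with TRAV7D-2 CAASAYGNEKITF). The largest had 55 cells (4.48%) in 5XFAD-2, 49 (2.33%) in WT-2, 24 (1.68%) in PS19 and 20 (4.47%) in WT-1. In WT-1, 80 of the 96 cells in expanded clones carried receptors of other pools. Its clone of 20 cells is larger than all that is left, so it held such cells and does not stand for WT mice. Of the PS-5X clone 73.2% and of the 5XFAD-1 clone 54.6% of cells sat in the cluster marked by Ccl3, Ccl4, Pdcd1, Rgs16 and Lag3. In that cluster 52.7% to 79.5% of cells were in expanded clones across the 6 pools, whereas the cluster marked by Ccr7, Dapl1 and Actn1, genes of naive T cells, held 0% to 1.72% and the second naive cluster, marked by Dapl1, Actn1 and Tdrp, 0% to 5.2%.

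CD4 T cells differed less evenly. In expanded clones were 26.0% (21.9 to 30.5) in 5XFAD-1, 8.09% (5.44 to 11.5) in 5XFAD-2 and 19.6% (17.2 to 22.3) in PS-5X against 5.41% (2.36 to 10.4) in WT-1, 10.3% (8.20 to 12.8) in WT-2 and 9.51% (7.12 to 12.4) in PS19. The difference was 9.50 points (17.9 ± 9.08% against 8.42 ± 2.64%, SD, n = 3 each, exact permutation test, two-sided, p = 0.30). It was 15.4 points within the common run and -2.24 within the separate run, 7.99 without WT-1, and 5.45 to 14.4 with each pool left out in turn. In 5XFAD-1 the largest CD4 clone alone had 41 cells (9.79%, 7.11 to 13).

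Expanded CD8 T cells expressed inhibitory receptors and effector molecules and had less RNA of naive-cell genes in every pool. Pdcd1, the PD-1 receptor, was at 428 ± 60.1 CPM (mean ± SD, n = 6 pools) in cells of expanded clones and 115 ± 19.2 in singletons of the same pools (log2 1.89, edgeR adjusted p = 6.8e-12, higher in 6 of 6 pools). Most WT-1 cells in expanded clones, 80 of 96, carried receptors of other pools, so WT-1 is not an independent pool here. Rgs16 (2.19), Lag3 (1.96), the granzymes Gzma (1.99) and Gzmb (1.74), the chemokines Ccl3 (1.74) and Ccl4 (1.63), Ildr1 (1.72), Ier5l (1.55) and Plscr1 (1.49) also rose in 6 of 6 pools. The homing gene Ccr7 (-3.69) fell in all 6, as did Igfbp4 (-5.86), Il6ra (-4.42), Dapl1 (-3.43), Tdrp (-3.42), Actn1 (-3.20), Nsg2 (-3.00), Cmah (-2.65) and Plaur (-2.50). In all, 3241 of 10956 genes differed (1696 higher, 1545 lower), beside 30 T cell receptor genes that are not counted because clones define the groups. DESeq2 called 2324, and edgeR with 1 pool left out 2687 to 3183. Expanded cells also sat in other clusters. They were 52.7% to 79.5% of the cluster marked by Ccl3, Ccl4 and Pdcd1 and 0% to 1.72% and 0% to 5.2% of the naive clusters. These sums therefore mix cluster shares with levels per cell.

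By list, all 16 inhibitory receptor and exhaustion genes were higher in expanded cells (Pdcd1, Lag3, Tox, Entpd1; 16 over the list alone), as were 15 of 15 tissue residency genes (Cxcr6, Bhlhe40, Rgs1, Cdh1, 15 alone) and 20 of 22 cytotoxic effector genes with 1 lower (Ifng, Id2, Ccl3, Gzmk, 20 and 1 alone). Of naive and central memory genes 15 of 16 were lower (Igfbp4, Actn1, Lef1, Ccr7, 15 alone). Lower too were 12 of 13 mitochondrially encoded genes (mt-Nd2, mt-Nd4l, mt-Nd1, mt-Atp6, 13 alone). Early T cell receptor response genes had 11 of 18 higher and 0 lower (Irf4, Nr4a2, Dusp2, Nfatc1, 12 alone), and interferon γ and antigen presentation genes 12 of 23 higher and 3 lower (Psmb9, Tap1, H2-K1, Psmb8, 14 and 3 alone). Camera with an estimated correlation kept the exhaustion, naive and early response lists (adjusted p = 0.0249 each), residency (0.0300), mitochondrial (0.0320) and interferon γ (0.0453). The cytotoxic list (median log2 0.77, adjusted p = 6.4e-09 with the preset correlation) had adjusted p = 0.205 with an estimated correlation. Other lists passed with the preset correlation alone: type I interferon (adjusted p = 0.0150, 0.474 estimated), dissociation and heat shock (0.0211, 0.474 estimated) and chemokine receptors and integrins (0.0406, 0.556 estimated). Of dissociation and heat shock genes 12 of 22 were higher and 2 lower (median 0.25; Fosb, Dusp1, Ier3, Btg2; 13 and 4 alone), and of chemokine receptors and integrins 10 of 16 were higher and 3 lower. Markers of other cells moved too. All 3 measured B and plasma cell genes differed, Ighm (-2.11) and Cd79b (-1.93) lower and Igkc (0.59) higher (camera adjusted p = 0.113), and of microglia and macrophage genes Lgals3 (0.89), Ctsd (0.57), Cst7 and Cst3 were higher and Cd9 (-0.71) and Ctss lower. Of 7 NK cell genes Fcer1g (-2.44) and Klra7 (-2.33) were lower (0.0738).

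**Figure D3:**
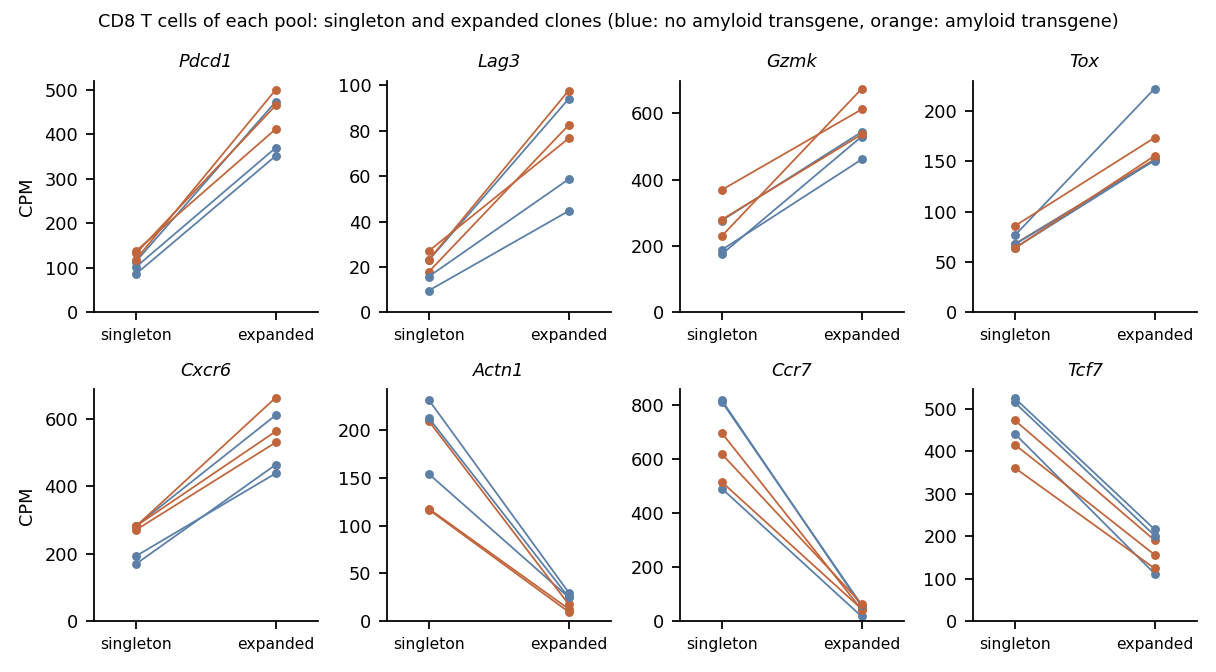
CPM of 8 genes in singleton and expanded CD8 T cells, 1 line per pool (n = 6, orange with, blue without the amyloid transgenes). Pdcd1, Lag3, Gzmk, Tox and Cxcr6 were higher and Actn1, Ccr7 and Tcf7 lower in expanded cells of every pool. In WT-1, 80 of the 96 expanded cells carried receptors of other pools, so its line is not independent of the others.

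Across all CD8 T cells, the amyloid transgenes went with more inhibitory receptor, residency and interferon-response RNA. However, the main edgeR fit, with the gene filter and without the replicate block, called no gene (70 by DESeq2). No list passed with an estimated correlation. The clusters within the class moved as well. The naive clusters marked by Dapl1 and Actn1 held 6.01% of CD8 T cells in 5XFAD-1, 18.7% in 5XFAD-2 and 14% in PS-5X against 16.2% in WT-1, 23.8% in WT-2 and 29.0% in PS19. The cluster marked by Cxcl10, Ifit3 and Rsad2 held 9.62%, 5.45% and 14.9% against 5.96%, 1.95% and 2.48%, so sums over all CD8 T cells mix cluster shares with levels per cell. Pdcd1 was at 255 ± 9.76 CPM (mean ± SD, n = 3 pools) with amyloid and 164 ± 22.8 without (log2 0.65 ± 0.10 SE, edgeR adjusted p = 0.179, higher in 3 of 3 pairs of pools; 0.0186 with the replicate block; DESeq2 5.4e-05). Similar were the chemokine Xcl1 (0.58 ± 0.09; 362 ± 11.9 against 243 ± 24.9 CPM, blocked adjusted p = 0.0174), Gzmk (0.59 ± 0.11, blocked 0.0143), the inhibitory receptor Lag3 (0.94 ± 0.19, blocked 0.0174), the integrin Itgae (0.86 ± 0.15, blocked 0.0174), Cxcr6 (0.54 ± 0.11, blocked 0.0383) and the interferon-induced genes Ifitm3 (3.03 ± 0.41; 25.3 ± 10.3 against 3.58 ± 2.30 CPM, blocked 0.0143) and Iigp1 (1.06 ± 0.16, blocked 0.0174), all higher in 3 of 3 pairs. In the other direction stood Cx3cr1 (-1.61 ± 0.29, blocked 0.0280) and S1pr5 (-1.64 ± 0.30, blocked 0.0143), which mark circulating cells, lower in 3 of 3 pairs. The cluster marked by both genes and Gzma held 18.1% of CD8 T cells in WT-2 and 3.11% to 8.03% in the other pools. Without WT-2 Cx3cr1 was at -1.10 ± 0.22 and S1pr5 at -1.10 ± 0.22, with adjusted p = 0.342 each.

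In numbers, edgeR called 0 of 11661 genes for amyloid in CD8 T cells (smallest adjusted p = 0.163), with 1206 at unadjusted p under 0.05 (655 higher, 551 lower) and 70 by DESeq2 (53 higher, 17 lower). With the replicate block, the sequencing run, 138 genes passed (93 higher, 45 lower). The granzymes Gzma (-1.06 ± 0.46) and Gzmb (0.08 ± 0.37) had no common direction: Gzma was 303 CPM in 5XFAD-1 and 83.5 in 5XFAD-2. The count was 121 without 5XFAD-2, 43 without WT-1, 1 without 5XFAD-1 and 0 without any other pool. With the replicate block and no WT-1 it was 85.

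**Figure D4:**
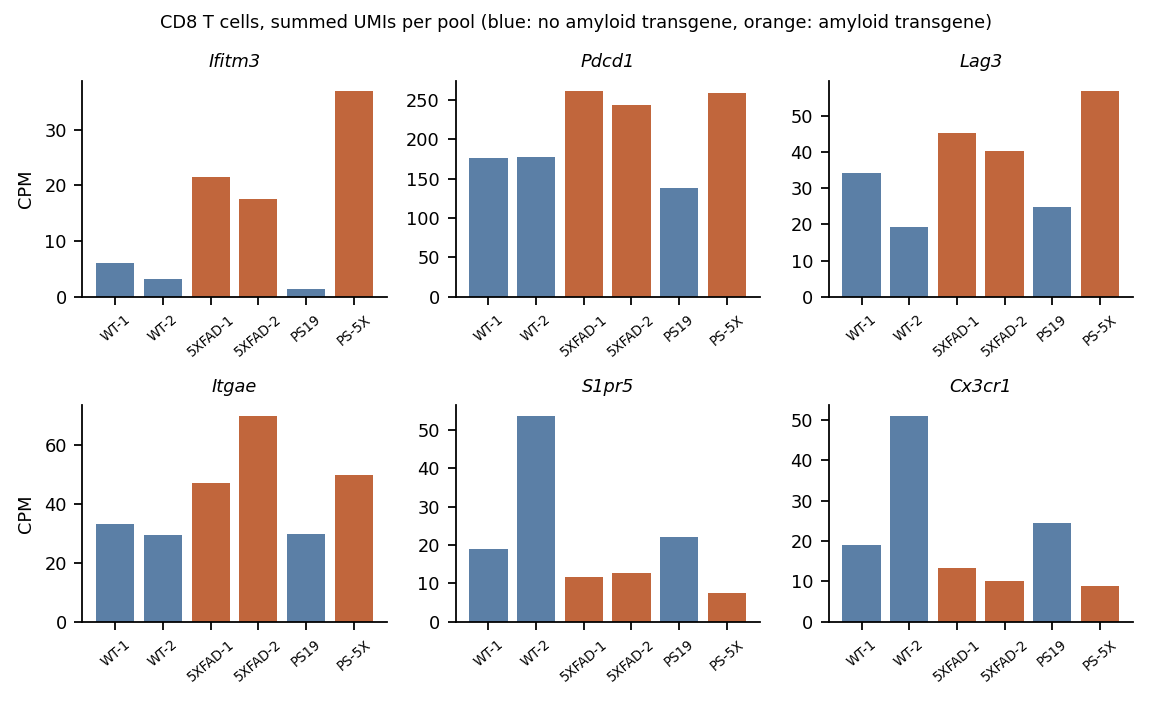
CPM of 6 genes in the CD8 T cells of each pool, 1 bar per pool (orange with, blue without the amyloid transgenes). Ifitm3, Pdcd1, Lag3 and Itgae stood higher in the 3 amyloid pools than in the 3 others, and S1pr5 and Cx3cr1 lower.

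Camera with its preset correlation called 8 of 15 lists, and 0 with estimated correlations (adjusted p = 0.276 to 0.389 for the 8). With the replicate block 8 passed, and with 1 pool left out 7 to 9. Inhibitory receptor and exhaustion genes were shifted up (median log2 0.35, adjusted p = 4.6e-06; 7 of 16 higher over the list alone, Pdcd1, Lag3, Tigit, Entpd1), as were tissue residency (0.49, 5.4e-09; 9 of 15, Xcl1, Itgae, Cxcr6, Litaf), type I interferon response (0.62, 1.6e-06; 17 of 24 higher and 3 lower, Bst2, Isg20, Xaf1, Rsad2), interferon γ and antigen presentation (0.28, 2.7e-09; 13 of 23, Iigp1, Psmb8, H2-T23, Irgm1) and early T cell receptor response (0.32, 0.000245; 6 of 18, Myc, Irf4, Dusp2, Tnfrsf9). Naive and central memory genes were shifted down (-0.47, 5.3e-09; 13 of 16 lower, S1pr1, Klf2, Txk), with NK cell genes (-1.17, 8.7e-06; 5 of 6, Tyrobp, Klra8, Klrb1c, Klra7) and mitochondrially encoded genes (-0.12, 0.0182; 0 of 13). Over all genes 0 of each list passed. The cytotoxic effector list did not pass (0.19, 0.0947; 8 higher and 4 lower alone), nor did dissociation and heat shock (0.604), chemokine receptors and integrins (0.337), cell cycle (0.767), glycolysis (0.475), microglia and macrophage (0.475) or B and plasma cell (0.521). The brain parenchyma list had 1 measured gene and the red blood cell list 0, so neither was tested. Red blood cell UMIs were 16 in the WT-1 CD8 sum and 0 to 4 in the others.

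Ifitm3 also led the comparison of 5XFAD with WT alone, 2 pools each. It was 21.5 CPM in 5XFAD-1 and 17.6 in 5XFAD-2 against 6.01 in WT-1 and 3.25 in WT-2 (Ifitm3 log2 2.25 ± 0.27 SE, edgeR adjusted p = 0.289, n = 2 and 2; DESeq2 adjusted p = 8.8e-05). Myc, a growth regulator, followed (0.71 ± 0.12, edgeR adjusted p = 0.774; DESeq2 0.0437), with the NK receptor Klrb1f in the other direction (-1.88 ± 0.32). edgeR called 0 of 12127 genes, 421 stood at unadjusted p under 0.05, and DESeq2 called 2, Ifitm3 and Myc. The replicate block leaves 1 residual degree of freedom and gave 208 calls (117 higher, 91 lower). Among them was Gzma (blocked edgeR adjusted p = 6.0e-25), although its 2 pairs of pools went opposite ways (log2 0.16 and -2.97). The spread of that fit is therefore not reliable, and its calls are not read as results. Without 5XFAD-1 the count was 21, without 5XFAD-2 28, and without WT-1, WT-2 or either tau pool 0. Leaving out a 5XFAD or WT pool leaves 1 pool on that side, so the spread then comes from the other genotype alone.

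For the tau transgene no CD8 gene passed, and heat shock genes leaned lower. Fosb, an immediate early gene, was 45.2 CPM in PS19 and 60.9 in PS-5X against 77.0 to 110 in the 4 pools without tau (log2 -0.81 ± 0.08 SE, edgeR adjusted p = 0.0748; 0.0101 with the replicate block). Irf2bp2 was higher (0.74 ± 0.10, edgeR adjusted p = 0.157, blocked 0.0389). edgeR called 0 of 11661 genes, with 739 at unadjusted p under 0.05 and 28 by DESeq2 (12 higher, 16 lower). The replicate block gave 29 (6 higher, 23 lower), the replicate block without WT-1 2, and leaving out 5XFAD-2 2. All 22 dissociation and heat shock genes had a negative log2 value (median -0.30, camera adjusted p = 5.3e-10; 7 lower over the list alone, Fosb, Hspa1a, Hspa1b, Dnaja1), and cytotoxic (0.00424), exhaustion (0.00424), NK cell (0.0116) and early T cell receptor response lists (0.0221) were also shifted down. Each had adjusted p = 0.399 with an estimated correlation. Handling of a pool can move heat shock genes as well, and tau rests on 1 pool without and 1 with amyloid, of a line on a mixed background. In γδ T cells edgeR called 13 of 8603 genes for tau (3 higher, 10 lower, with Hspa1a, Hspa1b and Jun among the lower; 514 at unadjusted p under 0.05, 17 by DESeq2, 26 with the replicate block). That count was 0 without PS-5X, 8 without PS19, 24 without 5XFAD-1 and 15 without WT-1. Leaving out PS19 or PS-5X leaves 1 pool with tau, so the spread then comes from the pools without tau alone. In CD4 T cells edgeR called 0 of 10127 for tau (503 at unadjusted p under 0.05, 11 by DESeq2, 22 with the replicate block). The amyloid by tau interaction was called for 0 genes in CD8 (245 at unadjusted p under 0.05), CD4 (208) and γδ T cells (312) by edgeR. Without WT-1, which leaves 1 WT pool, genes called in γδ T cells included Stmn2, Ccl5 and the αβ receptor genes Trbv3, Trbv13-2 and Trbv13-3.

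PS-5X against PS19 and other single pools were compared by values only, without a test. In CD8 T cells several interferon-induced genes were higher in PS-5X than in PS19: Rsad2 55.3 CPM (52.4 to 58.2, exact Poisson interval) against 6.55 (5.14 to 8.23) in PS19, log2 3.08, Cxcl10 166 (161 to 171) against 26.6 (23.6 to 29.7), log2 2.64, and Ifit3 159 (155 to 164) against 34.0 (30.7 to 37.6), log2 2.23. Ifi213, also induced by interferon, was lower (29.5 against 72.4 CPM, log2 -1.30). The cluster marked by Cxcl10, Ifit3 and Rsad2 held 609 of 4082 CD8 T cells in PS-5X (14.9%) and 38 of 1531 in PS19 (2.48%). Selenop was 30.7 (28.6 to 32.9) against 87.6 (82.2 to 93.2), log2 -1.51. Of 2711 genes at 50 CPM or more, 31 had a log2 ratio over 1 and 14 under -1, and 95% lay within 0.59. Between the 2 WT pools 95% lay within 0.51 and between the 2 5XFAD pools within 0.42. PS-5X against 5XFAD-1 had Cxcl10 at log2 1.92 (166 against 43.7 CPM, 40.1 to 47.7) and the heat shock gene Hspa1a at -1.74 (85.5, 82.0 to 89.1, against 285, 276 to 295). In PS19 against WT-2 Gzma was 161 (153 to 168) against 651 (637 to 665), log2 -2.02, and Gzmb 97.4 (91.7 to 103) against 299 (290 to 308), log2 -1.62. Against WT-1, which carries PS19 receptors, Eno1b was highest (60.5, 56.0 to 65.2, against 21.7, 17.3 to 26.9, log2 1.48). These CPM are per total UMIs of the class, without TMM.

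In CD4 T cells 1 gene rose with amyloid, Ly6a (Sca-1, an interferon-induced surface protein): 365 ± 31.8 CPM against 144 ± 9.35 (mean ± SD, n = 3 pools each; log2 1.34 ± 0.11 SE, edgeR adjusted p = 0.00252, higher in 3 of 3 pairs). Just outside were Sostdc1 (4.29 ± 0.60; 20.3 ± 12.4 against 0.69 ± 0.79 CPM, with 0 UMIs in WT-1), the cystatin Cst7 (1.01 ± 0.14) and the serpin Serpina3g (1.14 ± 0.17), each at edgeR adjusted p = 0.0989. With the replicate block they had 0.0123, 0.0153 and 0.0123. Lag3 (2.19 ± 0.44, blocked 0.0163) and Gzma (4.22 ± 1.27, blocked 3.9e-06) leaned on 5XFAD-1, where Gzma was 749 CPM against 22.9 in 5XFAD-2 and 46.5 in PS-5X. edgeR called 1 of 10127 genes, DESeq2 7 (5 higher, 2 lower), and the replicate block 19 (17 higher, 2 lower). At unadjusted p under 0.05 stood 693. With classes from the UMIs of each cell Ly6a was not called (log2 1.19 ± 0.21, edgeR adjusted p = 0.756). Without WT-1 or without WT-2 the count was 0, without 5XFAD-2 97, without 5XFAD-1, PS19 or PS-5X 3, and with the replicate block and no WT-1 41. Camera shifted the cytotoxic (median log2 0.86, adjusted p = 6.8e-08; 15 of 21 higher over the list alone, Cst7, Ccl4, Prf1, Ctsw), exhaustion (0.68, 6.0e-07; 10 of 15, Lag3, Cd160, Entpd1, Cd101) and type I interferon lists up (0.31, 7.5e-05; 9 of 24 higher and 3 lower alone, 1 over all genes, Ly6a), with adjusted p = 0.328, 0.293 and 0.293 with an estimated correlation. Shifted up too were interferon γ and antigen presentation (0.17, 0.000269), early T cell receptor response (0.24, 0.00422) and tissue residency genes (0.32, 0.00452), and naive and central memory genes were shifted down (-0.37, 2.7e-05), all with adjusted p = 0.293 to 0.445 with an estimated correlation. The cytotoxic genes leaned on 5XFAD-1, with Ccl5 at 6270 CPM there against 916 in 5XFAD-2, 1332 in PS-5X and 1362 in WT-1, and Gzmb at 384 against 21.5 and 159 in the other amyloid pools. The cluster marked by Gzma, Gzmb and Havcr2 had 79 of its 86 cells in 5XFAD-1. Without 5XFAD-1 the cytotoxic list had adjusted p = 0.000235 with the preset correlation. Markers of other cells moved with these lists. The microglia and macrophage list was shifted up (0.25, 0.00640; 7 of 8 positive, Cst7 and Spp1 first, of which Cst7 is also in the cytotoxic list), with 0.293 with an estimated correlation and 0.230 without 5XFAD-1. Cd8a was at 68.7 ± 26.8 CPM against 32.7 ± 7.49 in the CD4 sums (log2 1.08, edgeR adjusted p = 0.572, higher in 3 of 3 pairs).

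γδ T cells of the amyloid pools had more RNA of 12 genes, immediate early genes among them. Egr1 was at 492 ± 237 CPM against 180 ± 44.4 (mean ± SD, n = 3 pools each; log2 1.42 ± 0.19 SE, edgeR adjusted p = 0.00402, higher in 3 of 3 pairs) and Jun, an AP-1 subunit, at 1366 ± 422 against 729 ± 256 (0.92 ± 0.12, edgeR adjusted p = 0.00402, 3 of 3). Nfkbiz (1.28 ± 0.24, DESeq2 adjusted p = 0.970), Nfkbia (0.95 ± 0.16), Icam1 (1.37 ± 0.23), the stress-response genes Gadd45b (0.95 ± 0.16) and Zfp36 (0.94 ± 0.15), Ptgs2 (1.08 ± 0.18), Qpct (1.52 ± 0.29, DESeq2 adjusted p = 0.322) and AW112010 (0.92 ± 0.17) also rose in 3 of 3 pairs. Jun was at 882 CPM in PS-5X, between WT-1 (900) and WT-2 (852), so its rise there was mainly against PS19 (435). Ptgs2, at 208 CPM in PS-5X, lay below WT-1 (249). The other genes listed so far stood higher in each amyloid pool than in each other pool. With tau, Jun was lower (log2 -0.93 ± 0.13 SE). With classes from the UMIs of each cell AW112010 was at -0.16. The remaining 2 calls, Fos and Trbv16, were outside the 10 that the naming rule picks. Trbv16, an αβ receptor gene, had 81 of its 111 UMIs of the amyloid pools in cells with an αβ receptor contig. Cd69, an activation marker, was at 0.77 ± 0.17 (edgeR adjusted p = 0.110; 0.0236 with the replicate block).

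The γδ count was 12 of 8603 genes, 12 higher and 0 lower, with 463 at unadjusted p under 0.05 and 13 by DESeq2 (11 higher, 2 lower). The replicate block gave 32 (28 higher, 4 lower). It was 0 without WT-2, 1 without PS19, 1 without PS-5X, 28 without 5XFAD-1 and 19 without WT-1, where 8 of the 12 stayed called. The replicate block without WT-1 gave 62. With doublets kept 5 genes were called, 4 of the 12 among them, and with classes from the UMIs of each cell 8 genes, again with 4 of the 12. In each of these fits 1 of the 12 had the opposite sign. Dissociation and heat shock genes (median log2 0.31, camera adjusted p = 2.5e-05; 3 of 21 higher over all genes and 11 over the list alone, Jun, Fos, Zfp36, Dusp1) and early T cell receptor response genes (0.64, 6.5e-05; 2 of 16 and 6 alone, Egr1, Nfkbia, Nr4a1, Cd69) were shifted up, both with adjusted p = 0.435 with an estimated correlation. Naive genes were shifted down (-0.71, 0.000398; 0 of 13 and 1 alone, Klf3, Actn1, Lef1, Txk), also 0.435. Shifted up too were tissue residency (0.42, 0.00177), cytotoxic (0.45, 0.00223) and interferon γ genes (0.12, 0.0243), with 0.374 to 0.455. The amyloid effect differed between γδ and CD8 T cells in 29 genes (18 higher and 11 lower in γδ; Egr1, Jun, Zfp36 and Nfkbia among them; 54 genes without WT-1) and between γδ and CD4 T cells in 6 (Jun, Zfp36, Fos and Gadd45b among the 5 higher; 12 genes without WT-1). T cell receptor genes are counted in both sets: Trbv16, Trbv31, Trav9-1, Trdv4 and Tcrg-C4 were among the 29 and Trbv31 among the 6. Pools held 38 (WT-1) to 279 (PS-5X) γδ T cells.

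**Figure D5:**
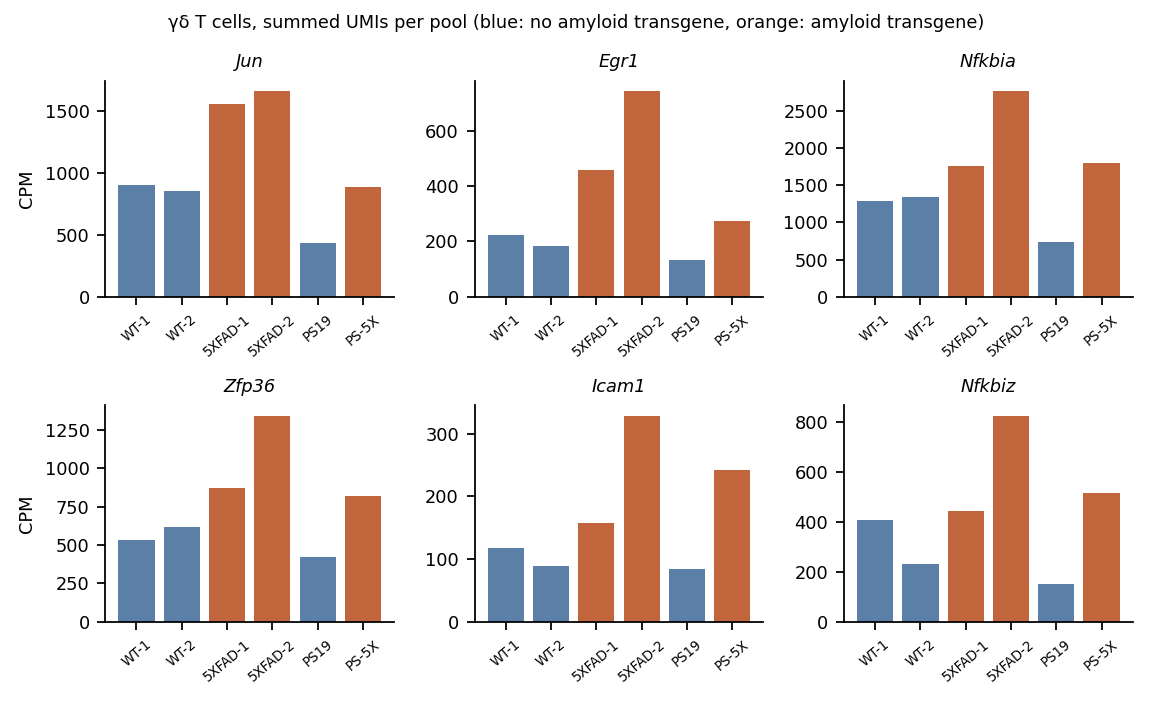
CPM of 6 genes in the γδ T cells of each pool, 1 bar per pool (orange with, blue without the amyloid transgenes). Jun, Egr1, Nfkbia, Zfp36, Icam1 and Nfkbiz rose with the amyloid transgenes in 3 of 3 pairs of pools. Jun in PS-5X (882 CPM) lay between WT-1 (900) and WT-2 (852).

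In V gene usage of CD8 clones, each clone counted once, no gene passed for amyloid. Of 59 TRAV and TRBV genes edgeR called 0, with 5 at unadjusted p under 0.05 and 0 with DESeq2 size factors. Lowest was TRAV12D-3, at 0.24% of clones in 5XFAD-1, 0.58% in 5XFAD-2 and 0.62% in PS-5X against 1.86% in WT-1, 1.14% in WT-2 and 1.79% in PS19 (log2 -1.66 ± 0.61 SE, edgeR adjusted p = 0.198). TRBV19 was at -0.32 ± 0.12 and TRBV14 at 0.49 ± 0.21. The replicate block called 0, as did each fit with 1 pool left out.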

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

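The difference without WT-1 and the fit at equal UMI sums were planned, and the other tests here were chosen after the patterns were seen. How to read the tests of barcode swapping, of independently made receptors, of 1 mouse in WT-1 and PS-5X, of mouse numbers, of handling, depth and Trbv16 in γδ T cells and of the splits was also written after their values were known, and for the others before.

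WT-1 cells carrying receptors of other pools, 169 in all, and the 6 receptors shared by PS19 and PS-5X point to mixed cells or libraries. If cells of another pool had entered WT-1 in proportion to clone size, 19 to 28 of the 37 large clones of 5XFAD-1 would be found there, and 23 were; for PS19 the range was 8 to 14 of 23 and 10 were found, which argues against 1 mouse present in both pools for these 2. For PS-5X 1 was found against 2 to 3, from 3 cells, as 1 mouse in both pools would give, so this stays open there. WT-1 cells with a 5XFAD-1 receptor shared a cell barcode with that clone in 0 cases, which argues against barcode swapping, and the 10 pairs of pools without WT-1 had 6 shared receptors, all in PS19 with PS-5X, an upper limit of 0.234 per 1000000 pairs of cells against 55.4 for WT-1 with 5XFAD-1, which argues against the same receptor made independently. From the large clones, cells of 5XFAD-1 would make up 41.6% (33.1 to 51.4) and those of PS19 28.5% (16.7 to 45.1) of WT-1. Where such mixing would have happened, before or after the sort, stays open, and so does how far WT-1 stands for WT mice.

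The 12 genes higher in γδ T cells of the amyloid pools, with Jun and Egr1 first, include immediate early genes that handling can move. Between lineages, 29 genes differed in their amyloid effect from CD8 and 6 from CD4 T cells, with T cell receptor genes in both sets. The 12 were picked in γδ T cells, so how many of them differ says little. Handling that moved all T cells alike would raise them as much in the other lineages. The 11 measured there had a median log2 value of 0.094 in CD8 (SD 0.283) and 0.131 in CD4 T cells (SD 0.319), below the 0.953 of the same genes in γδ T cells by more than the SD, which argues against it, though values of genes picked in γδ T cells can be too high there. At equal UMI sums 10 of 11 tested stayed called, which argues against depth, and with αβ receptor cells left out the median log2 value of 11 genes was 1.03, against 0.953 for the same genes with them, which argues against αβ T cells inside the cluster for these. Of the 11, 8 stayed called, and Qpct (1.52 ± 0.29 before, 1.35 ± 0.32 after), Gadd45b (0.95 ± 0.16, 0.96 ± 0.20) and AW112010 (0.92 ± 0.17, 1.01 ± 0.21) lost their call as the SE grew, with a smaller value for Qpct. The remaining gene, Trbv16, is an αβ receptor gene with 81 of its 111 UMIs of the amyloid pools in those cells, as αβ T cells inside the cluster would give. Handling to which γδ T cells alone respond stays open. The count was as high or higher in 2 of the 10 splits of the 6 pools, so these splits cannot settle it.

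The higher share of CD8 T cells in expanded clones in the amyloid pools was set against 3 explanations. Mouse number cannot be told apart from amyloid, since PS19, at 24.0%, was the only pool of 4 mice without amyloid and 1 pool gives no spread between pools. At the same number of cells per mouse, WT-1 left out of the draw, the difference was 11.3 points, and over all cells of the same 5 pools 15.5 points, which argues against sampling depth and against the mixed WT-1 pool as the whole cause. A smaller share of naive cells in the amyloid pools is a further explanation and was not tested. The naive clusters had 0% to 5.2% of their cells in expanded clones. They held 6.01% to 18.7% of CD8 T cells in the amyloid pools and 16.2% to 29.0% in the others. How much of the difference comes from naive cells stays open. The pattern may follow the amyloid transgenes, but p = 0.10 in the exact permutation test is the smallest that 3 against 3 pools allow. Which antigens drive the clones stays open.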

How the results depend on the processing

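Fits without the WT-1 cells that carry shared receptors, fits without γδ cluster cells with an αβ receptor, fits with the replicate block and no WT-1, the means of the differences within runs and the splits were chosen after the data were seen. So was everything on the CD4 share of T cells, on lists in CD4 T cells, on tau in CD4 and γδ T cells, on the interactions and on the differences between lineages. The others were fixed before. The cause of the differences was not tested.

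With DESeq2 the CD8 amyloid count was 70, tau 28, 5XFAD against WT 2 and CD4 7. Without a gene filter the counts were 550 for CD8 amyloid, 241 for tau, 103 for 5XFAD against WT, 203 for CD4 and 99 for γδ. For CD8 amyloid Cx3cr1 was -1.61 with and -1.60 without the filter, while its SE fell from 0.29 to 0.13 (unfiltered edgeR adjusted p = 1.3e-31). S1pr5 moved alike. Both calls came from a smaller estimated spread and not a larger effect. The CD8 count is therefore not read as genes that the filter hid. The replicate block gave 138, 29, 208, 19 and 32, raised tau from 0 to 22 in CD4 T cells and from 13 to 26 in γδ T cells, where 9 of the 13 stayed called, and left the 8 lists and 0 V genes as they were. The 208 rest on 1 residual degree of freedom and include Gzma, whose pairs of pools went opposite ways, so they are not read as results. The shares have no such test, and the CD4 expansion difference was 15.4 points within the common run and -2.24 within the separate run. The replicate block with WT-1 left out gave 85 for CD8 amyloid, 2 for tau, 41 for CD4 and 62 for γδ. For 5XFAD against WT it leaves no residual degrees of freedom and was not run. At thinned UMIs CD8 amyloid had 2 and tau 4. With the same number of cells from each pool CD8 amyloid had 4, and without the WT-1 cells with shared receptors 58. That step also took out 80 of the 96 WT-1 CD8 T cells in expanded clones, so it shifts WT-1 toward singletons. With doublets kept, 5XFAD against WT had 1, CD4 9 and γδ 5. With classes from the UMIs of each cell CD4 had 0. Lists called fell to 0 of 15 with estimated correlations, and in CD4 T cells from 8 of 14 to 0.

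With each pool left out in turn, the counts ran from 0 to 121 for CD8 amyloid, 0 to 2 for tau, 0 to 28 for 5XFAD against WT, 0 to 97 for CD4, 0 to 28 for γδ and 2687 to 3183 for expanded against singleton, and the lists from 7 to 9 in CD8 and 6 to 9 in CD4 T cells. V genes stayed at 0. The shares ranged over 15.5 to 21.3 points for CD8 expansion, 11 to 14.4 at equal cell number, 5.45 to 14.4 for CD4 and -4.76 to -3.91 for the CD4 share of T cells.

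For tau, CD4 T cells had 0 calls and γδ T cells 13. DESeq2 gave 11 and 17, no gene filter 105 and 97, the replicate block without WT-1 147 and 19, and each pool left out 0 to 3 and 0 to 24. Leaving out WT-1 gave 54 genes that differed between γδ and CD8 T cells, 12 between γδ and CD4 T cells, and 6 for the amyloid by tau interaction in γδ T cells.

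The 158 named gene tests had 2237 values under alternatives. Of these, 1698 were called both times in the same direction, or called neither time and within 1 SE of the value they were compared with. A further 240 were called under the alternative alone, 64 lost their call, and 234 were called neither time and moved by over 1 SE. The opposite sign was seen in 77, of which 76 were called neither time and 1 had been called: AW112010 in γδ T cells, -0.16 with classes from the UMIs of each cell. Of 139 alternative counts 78 were equal or within 1.5 times, 50 were higher and 11 lower by more than that, and all 72 alternative shares kept their direction. No share of 3 against 3 pools can pass 0.05, so their calls could not change.

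Splits of the 6 pools into 3 and 3 number 10, too few for a test. At least as many genes were called in 10 of them for CD8 (real 0, highest other 33), in 6 for CD4 (1 and 41) and in 2 for γδ (12 and 25), and for V genes in 10 (0 and 1). For lists it was the real split alone, 1 (8 and 7). For CD8, CD4 and γδ the highest split set WT-1, 5XFAD-1 and PS-5X against the others, 33 against 0 for CD8 and 41 against 1 for CD4 in fits without the replicate block, which points to structure among the pools. Exchanging expanded and singleton sums within pools gave at least 3241 calls in 1 of 32 ways, the real one, and at most 192 in the others, in line with a difference tied to clone size.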

Other observations

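Receptors with the same amino acids arose in several pools from different nucleotides. There were 7 such α and β receptor pairs, each in 2 pools, counted only where no nucleotide version was in more than 1 pool. A further 2, with a version shared by WT-1 and 5XFAD-1, were left aside. The count was made after the pairs were seen. The largest, TRAV4-4-DV10 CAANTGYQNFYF with TRBV29 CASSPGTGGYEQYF, had 8 cells in WT-2 and 45 in PS-5X. Selection by a common antigen and sequences that are frequently made were not tested apart.

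A CD4 population with RNA of granzymes and exhaustion markers sat almost wholly in 1 pool. The CD4 cluster marked by Gzma, Gzmb and Havcr2 had 86 cells, 79 of them from 5XFAD-1, and the 2 largest CD4 clones of 5XFAD-1, of 41 and 24 cells, had 97.6% and 100% of their cells there. Pdcd1, Tox, Lag3, Havcr2, Tigit, Ctla4 and Entpd1, markers of exhausted T cells, were raised in it, each in at least 50% of cells. Cells with a TRAV11 to TRAJ18 rearrangement, the α chain of invariant NKT cells, were 4.23% (3.28 to 5.35) of cells with an α chain in 5XFAD-2 and 0.89% (0.63 to 1.22) to 2.21% (1.68 to 2.85) in the other pools. Without 5XFAD-1 Ly6a was among the 3 CD4 calls (log2 1.40, adjusted p = 0.000836), while it was not called without WT-1 (1.34, 0.0715), without WT-2 (1.31, 0.0553) or with classes from the UMIs of each cell (1.19, 0.756).

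With the replicate block, Cdh1, Ifitm3, Ly6a and Nme7 were called with amyloid in at least 2 of the 3 lineages at a log2 value of at least 1, all higher. Genes with smaller values, such as Lag3 (0.93 in CD8 T cells with the block), are not counted. Without the block 0 genes were called in this way. With tau and the block, Gm10501 and Gm46620 were called at a log2 value of -1 or below, both lower.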
